A study of Drosophila melanogaster with 4 samples.

How the data were processed

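RNA sequencing was done on 4 libraries of Drosophila melanogaster ovaries, 2 from wild type and 2 from RpS5b mutant females, dissected 48 hours after eclosion. Per the labels' protocols, RNA was extracted with TRIzol and the libraries were made with a stranded total RNA kit, while the molecule label reads polyA RNA. Per the submitters' processing notes, the tools named were Trim Galore 0.4.1, Bowtie 1.0.0, TopHat2 2.1.2, SAMtools 0.1.19, bedtools 2.26.0 and DESeq2, with the build BDGP6. The role and order of these tools are not given in the sources used here.

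Each deposited table held 1 row per transcript, with the count of reads, the coverage signal (counts per nucleotide) and the RPKM, per the file headers. The counts were made by the authors from the 5' end of each alignment of 25 to 100 nt, per the file headers. The deposited signal per nucleotide and the deposited RPKM values equalled the count divided by the row's length and, for RPKM, by the total given in the header, so they were not tested separately. Each transcript was counted by the authors on its own, per the file headers, so transcripts of the same gene share reads. The table header gave a total of 33955476 and 43040528 reads for wild type replicates 1 and 2, and of 48218060 and 38989829 for mutant replicates 1 and 2.

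Of 34729 transcripts, 34445 were matched by identifier to genes of the BDGP6 annotation (Ensembl release 115). All of the matched transcripts had the same strand as in the annotation and 99.67% had the same start and end, so coordinates are given on that build, counted from 1. The 284 unmatched transcripts held at most 0.391% of the counts of a library and were left out. Each of the 17533 genes was represented by its transcript with the largest total over the 4 libraries. Reads shared by transcripts of a gene were thus not counted more than once for it. For every row, exons of other genes on the opposite strand were found from the annotation, since most counts lay on rows with such exons. A gene with exons under a row on the other strand is called its opposite gene.

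Counts were tested with edgeR 4.0.16 in R 4.3.3. Rows were kept by filterByExpr with a minimum count of 10 and a minimum total of 15, library sizes were scaled by TMM, and mutant over wild type was tested with the robust quasi-likelihood F-test, two-sided. P-values were adjusted by the Benjamini-Hochberg method over the 5031 rows kept, and a row at an adjusted p under 0.05 is said to have risen or fallen. The common biological coefficient of variation was 0.145. TMM factors were 1.21, 1.13, 0.870 and 0.840 for wild type 1, wild type 2, mutant 1 and mutant 2. Levels are CPM values after TMM scaling, given as mean ± SD, and log2 fold changes are given with a standard error (SE) equal to their size over the square root of F. Gene lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, two-sided, adjusted over the 24 lists with at least 3 tested members, and again with an estimated correlation and with fry.

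The grouping, the test, 28 gene lists, the alternatives and the rule for naming genes were fixed before the data were examined. The rule named RpS5b and RpS5a, then the 10 largest increases and the 10 largest decreases among rows past the test with a mean of at least 10 CPM and no overlap between the groups. It further named up to 4 members of each list with the smallest adjusted p, and any member of the yolk, vitelline membrane, chorion, insulin and TOR, and early follicle cell lists. Rows lying opposite a listed gene, the row with the most counts, and LanB1, trol, dpy, TFAM, Pepck1, Gadd45, me31B, Tl, osk and Orc6 were named after their values were seen.

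Alternatives tried were median-of-ratios size factors, library totals alone, scaling without the yolk, vitelline membrane and chorion genes, no low-count filter, a stricter filter (10 counts in each library of a group and a mean of 5 CPM), DESeq2 1.42.0, a replicate block, leaving out each library, a minimum change of 1 on the log2 scale, and sums over all rows of a gene. Chosen after the data were seen were a fit of the rows without opposite-strand exons scaled among themselves, the header totals as library sizes, and a reading of each listed gene from the row opposite it (at least 100 nt of exon overlap and no other opposite gene). The latter could be had for 2032 genes.

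The fit was tested on simulated data with 200 changed genes added to counts drawn from the real means. Over all rows (5031 genes) it recovered 55.9% of changes of 2-fold and 96.3% of changes of 4-fold, with 11 false calls among 166. Over rows without opposite-strand exons (2272 genes) it recovered 28.6% and 93.6%, with 8 false calls among 136. The genes were drawn independently of one another, with increases and decreases equally likely. The false calls thus do not measure errors from scaling or from genes that shift together between libraries. Nothing in the labels says that replicates came from separate cohorts of flies, so p-values measure only the spread between these samples, which may be technical. Counting intervals are exact binomial 95% intervals and cover counting error only. A fold against a group at 0 counts was computed against 3 counts over the group. Footprint sequencing was not analysed here.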

Results

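RNA sequencing counts were analysed from 4 libraries of Drosophila melanogaster ovaries, 2 from wild type females and 2 from females mutant for RpS5b, a gene that encodes a protein of the small ribosomal subunit and has a paralog, RpS5a. Ovaries were dissected 48 hours after eclosion, and per the labels the egg chambers of stages 10 to 14, which are the late stages of oogenesis, were taken out of the control sample. The labels do not mention such a step for the mutant. A different mix of stages therefore cannot be told apart from the mutation in any row below. The file headers gave 33955476 and 43040528 reads for wild type replicates 1 and 2, and 48218060 and 38989829 for mutant replicates 1 and 2. The rows of 17533 genes held 736915, 964913, 1276000 and 1073385 counts, or 2.17, 2.24, 2.65 and 2.75% of those totals. Replicates differed by more than sampling noise, with a chi-square per degree of freedom of 4.97 in wild type and 4.30 in the mutant.

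In RpS5b mutant ovaries the yolk protein rows rose 6.92-fold to 15.7-fold. Of 7 tested rows of the vitelline membrane, the inner layer of the eggshell, 5 rose. The calls of both lists were lost with an estimated correlation (adjusted p = 0.88) and with fry. Of 84 rows of cytosolic ribosomal proteins 37 rose and 1 fell, and the call of that list was lost with an estimated correlation (adjusted p = 0.88) and with fry. Rows of the mitotic regulators fzy, CycB, CycA and polo fell, but camera did not call the mitotic list (adjusted p = 0.0506). The row opposite nanos, a germline and posterior patterning gene, fell 4.48-fold, while the own row of nanos rose. That opposite row belongs to CG11779, and 11.79% of its length overlaps nanos. The comparison asked which transcripts differ between these mutant and wild type ovaries. By edgeR's quasi-likelihood test with Benjamini-Hochberg adjustment, 801 rows were higher and 659 were lower in the mutant among 5031 tested, and 2046 had an unadjusted p under 0.05.

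Where counts lay limits what a row stands for. Only 11.0, 12.3, 9.74 and 11.2% of the counts of wild type 1, wild type 2, mutant 1 and mutant 2 lay on rows without an exon of another gene on the opposite strand. The row with the most counts, asRNA:CR45330 on chromosome 2L (13241807 to 13244724), overlaps an exon of snRNA:U2:34ABc on the other strand and took 9.77, 12.4, 14.7 and 17.8% of the counts in the same order of libraries. Wilson 95% intervals of these shares spanned at most 0.145 percentage points and cover counting error only. Yp1, on the plus strand of X (10053852 to 10055498), had 36 and 42 counts in wild type and 508 and 706 in the mutant on its own row. The antisense row asRNA:CR45601, which lies wholly inside Yp1 exons on the minus strand (X, 10054235 to 10055109), had 9641 and 9493 in wild type and 144608 and 113556 in the mutant. Across 31 non-coding rows with at least 90% of their length inside exons of 1 coding gene on the other strand, the log2 fold changes of the row and of that gene's own row had a Pearson r of 0.637 (permutation p = 0.00137) and a Spearman rho of 0.363 (permutation p = 0.0453). This correlation is across genes, which are not independent replicates, and without the 2 pairs farthest from the median r was 0.344, so it rested in part on those. Each value below is therefore the count of the row named, and an opposite gene is named wherever the row has one. On the same strand, the rows of Surf6, Ilp8, trol and Pepck1 overlap ClpX, lncRNA:CR45756, mir-4955 and CG45087, so their counts may be shared. A row opposite a gene may overlap it over a small part of its length, so its counts need not come from that gene. Of the 2148 tested rows without opposite-strand exons, 320 rose and 162 fell. Among all tested rows, 171 had the same 4 counts as another tested row and 50 of these were called, so such calls may count the same reads more than once.

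**Figure D1:**
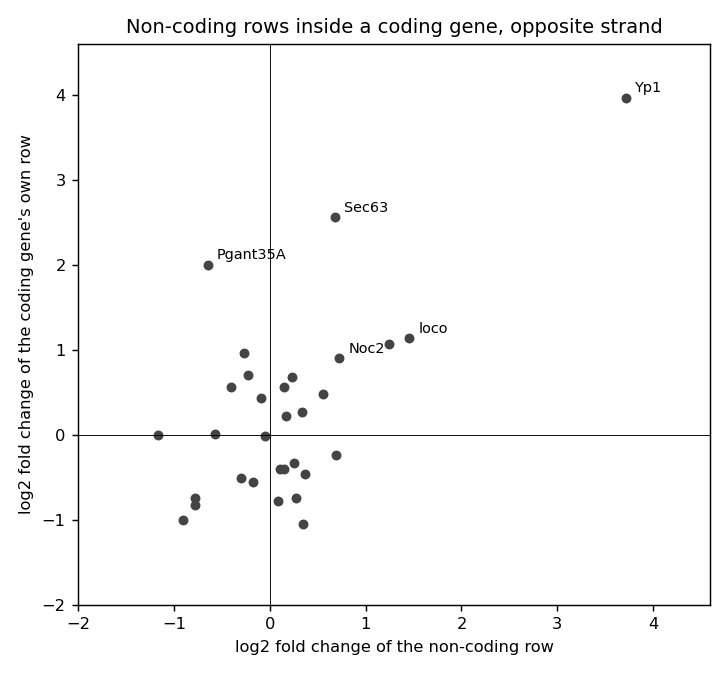
Each point is 1 of 31 non-coding rows inside the exons of a coding gene on the other strand, with its log2 fold change (mutant over wild type) on the x axis and that of the coding gene's own row on the y axis. The pair of asRNA:CR45601 and Yp1 lies at 3.71 and 3.97, far from the other pairs.

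RpS5b (FBgn0038277, 3R, 14900432 to 14901563, minus strand, no opposite gene) had 14 and 36 counts in the wild type libraries and 2 and 1 in the mutant libraries, which goes with the labels. Its level was 24.8 ± 12.4 CPM in wild type and 1.48 ± 0.501 CPM in the mutant (SD, n = 2 each), a log2 fold change of −3.95 (SE 0.67, adjusted p = 0.00106). The ratio of the summed counts after scaling was 16.9, with a 95% counting interval of 5.5 to 84.7. RpS5a (X, 17143588 to 17148264, no opposite gene) had 10 and 24 counts in wild type and 30 and 42 in the mutant, a log2 fold change of 1.09 (SE 0.40) that did not pass the test (adjusted p = 0.0583). It passed in alternatives that include leaving out wild type replicate 2 or mutant replicate 1, no low-count filter and the stricter filter.

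All 3 yolk protein genes rose. They encode the yolk proteins that fat body and follicle cells make and the oocyte takes up. Yp2 (X, 10051016 to 10052636, no opposite gene) went from 34.4 ± 8.07 to 424 ± 168 CPM, a log2 fold change of 3.60 (SE 0.30, adjusted p = 6.0e-06). Yp1 rose by 3.97 (SE 0.27) and Yp3, which has no opposite gene, by 2.79 (SE 0.38) on the log2 scale. The row opposite Yp1, asRNA:CR45601, rose by 3.71 (SE 0.17, adjusted p = 1.9e-08). Camera called the list (adjusted p = 2.3e-07), though not with an estimated correlation (adjusted p = 0.88) or with fry (adjusted p = 0.147, with alternatives from 6.1e-16 to 0.88). All 3 also rose when adjusted over the list alone. Of other fat body products, Lsp1beta had 6, 7, 3 and 3 counts and apolpp had 6, 0, 10 and 7, in the order wild type 1, wild type 2, mutant 1, mutant 2. Only 2 of 18 fat body genes passed the low-count filter (both rose when adjusted over the list alone), of which Obp44a (opposite gene Pabp2) rose by 0.80 (SE 0.22), a call lost without wild type replicate 2 or mutant replicate 2. The row opposite Obp44a was not called (log2 fold change 0.58, SE 0.36), and that opposite the other gene, Lsd-1 (CG10214), rose 4.13-fold.

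Of 7 tested rows of the vitelline membrane list, 5 rose and none fell, also when adjusted over the list alone, and the median log2 fold change was 2.02. Vm26Aa, a structural vitelline membrane protein, had 0 and 4 counts in wild type and 24 and 21 in the mutant. Its scaled ratio was 11.1 with a counting interval of 4.0 to 42.5. The eggshell gene dec rose 4.27-fold on its own row (log2 fold change 2.09, SE 0.25) and 3.31-fold on the row opposite it, asRNA:CR43615 (log2 fold change 1.72, SE 0.15). The serine protease gene ndl (opposite gene MCU) rose by 2.02 (SE 0.34), and Vm34Ca by 2.18 (SE 0.70), a call lost without wild type replicate 1 or mutant replicate 2. The row of clos also rose, from 10554 ± 865 to 15886 ± 791 CPM, but it overlaps RpL31 on the other strand, and its call was lost without mutant replicate 2. Camera called the list (adjusted p = 0.00959), but not with an estimated correlation (adjusted p = 0.88), with fry (adjusted p = 0.147), among the 3 rows without opposite-strand exons (adjusted p = 0.136) or without wild type replicate 1 (adjusted p = 0.0546, with alternatives from 0.00241 to 0.88). Without wild type replicate 1 4 rows rose, and without mutant replicate 2 only 3.

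Chorion genes, which build the outer eggshell in the last stages, moved little as a group. Of 10 tested, dec rose and Femcoat fell, the median log2 fold change was −0.07 while camera's direction was up, and the list was not called (adjusted p = 0.828). Adjusted over the list alone, 1 rose and none fell. Femcoat went from 15 and 15 counts to 5 and 6 (adjusted p = 0.0468) and lost its call when any of the 4 libraries was left out. Cp15 had 20 and 16 counts in wild type and 9 and 7 in the mutant and was not called (adjusted p = 0.0675), though it was without wild type replicate 2, with the stricter filter, and with library totals or header totals.

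**Figure D2:**
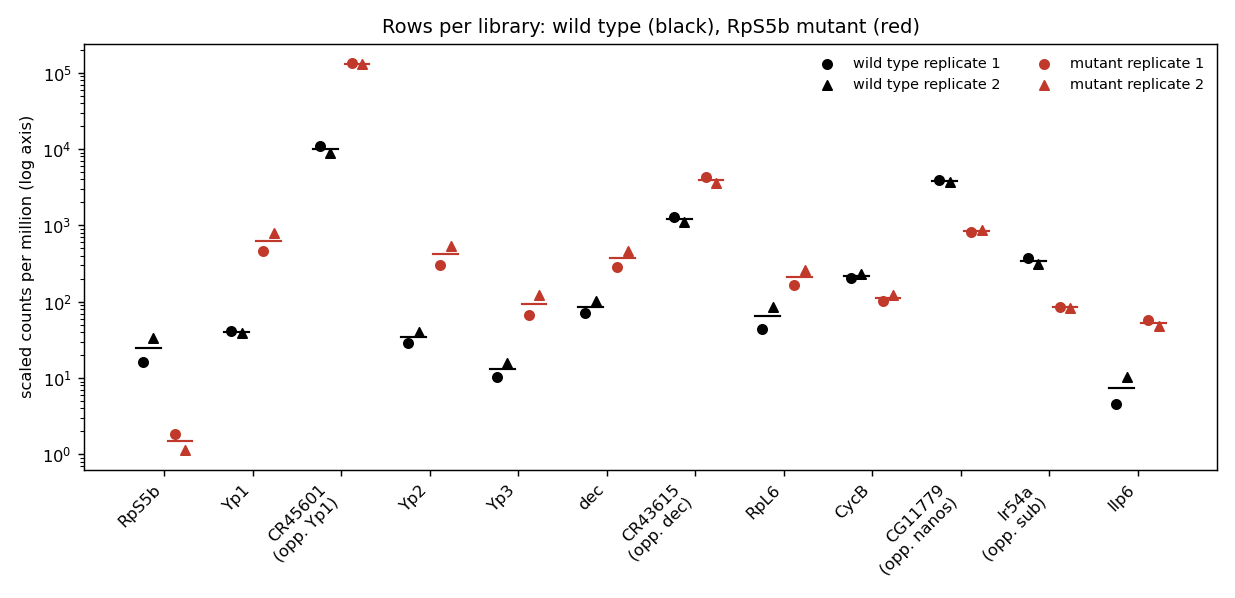
CPM (log axis) of 12 rows in each of the 4 libraries, with wild type in black and the RpS5b mutant in red, circles for replicate 1, triangles for replicate 2 and bars for group means. The row opposite Yp1 lies near 9945 CPM in wild type and 130538 CPM in the mutant, while that opposite nanos lies near 3775 and 843 CPM.

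Cytosolic ribosomal protein rows had a median log2 fold change of 0.96, with 37 higher and 1 lower among 84 tested. Adjusted over the list alone, 53 were higher and 1 was lower. RpL28 (opposite gene nSMase) rose by 3.05 (SE 0.27), RpL6 (3R, 31594792 to 31596204, no opposite gene) by 1.68 (SE 0.30) and RpLP2 (no opposite gene) by 1.08 (SE 0.23), the last call lost without wild type replicate 1. RpS20, whose row overlaps CG17272, fell by 1.48 (SE 0.22). The row opposite RpL24 (CG7099) rose by 0.88 (SE 0.24), a call lost without wild type replicate 2, and those opposite RpL27 and RpL30 did not pass the test. Beside these changes stood a spread between replicates: the list's median deviation from the mean of the 4 libraries was −0.76 in wild type 1, −0.10 in wild type 2, 0.11 in mutant 1 and 0.81 in mutant 2. Camera called the list (adjusted p = 5.5e-07), but not with an estimated correlation (adjusted p = 0.88), nor did fry (adjusted p = 0.314, with alternatives from 5.4e-23 to 0.88). Without wild type replicate 1 the median was 0.67 and 5 rows rose, without mutant replicate 2 it was 0.52 and 7 rose, and without mutant replicate 1 it was 1.32 and 56 rose. With library totals alone 14 rose, with counts summed over all rows of a gene 12 of 85, and among rows without opposite-strand exons 14 of 60.

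Of 31 genes of ribosome biogenesis 12 rose and 1 fell, also when adjusted over the list alone. Their median was 0.60 and the list did not pass (adjusted p = 0.0605, and 0.88 with an estimated correlation). It passed in 4 alternatives, without wild type replicate 2, without mutant replicate 1, with no low-count filter and among rows without opposite-strand exons (adjusted p = 0.0183, with alternatives from 0.00244 to 0.88). The nucleolar genes Surf6 (same-strand overlap with ClpX) and Nop56, both without an opposite gene, rose 3.03-fold and 2.42-fold, and pit rose by 1.15 (SE 0.25). Nop17l, which overlaps PolZ1, fell by 1.06 (SE 0.21). The rows opposite peng (dod), Tsr1 (Tbc1d8-9) and Nop10 (CG12935) rose by 0.97 (SE 0.13), 0.75 (SE 0.13) and 0.84 (SE 0.15), 3 of 4 such rows. With library totals alone 2 biogenesis rows rose and 3 fell, and only 4 rose without wild type replicate 1 or without mutant replicate 2. The 15 tested ribosomal protein genes with a second copy had a median of 0.50 (list adjusted p = 0.259), and the list was called without wild type replicate 2 (adjusted p = 0.0229) and without mutant replicate 1 (adjusted p = 0.00244, with alternatives from 0.00244 to 0.88). Among 38 translation factors, 6 rose and 2 fell, none rose and 1 fell when adjusted over the list alone, and the median of 0.42 turned to −0.03 with library totals alone (list adjusted p = 0.315). None of the factors rose without wild type replicate 1 or without mutant replicate 2, whereas 10 rose and the list was called without wild type replicate 2 (adjusted p = 0.00940) or without mutant replicate 1 (adjusted p = 0.0185, with alternatives from 0.00940 to 0.88).

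Of 15 tested mitotic genes, 4 fell and none rose over all rows, 7 fell and 1 rose when adjusted over the list alone, and the median was −0.86. Scaled by library totals alone, 10 fell. CycB, a mitotic cyclin with no opposite gene (2R, 22803521 to 22806948), had 179 and 249 counts in wild type and 111 and 110 in the mutant, a log2 fold change of −0.96 (SE 0.20, adjusted p = 0.00353). The row of fzy, an activator of the anaphase-promoting complex (opposite gene cact), fell by 1.70 (SE 0.17). CycA fell by 0.84 (SE 0.25) and the kinase gene polo by 1.07 (SE 0.33), both without an opposite gene, and both lost their calls without wild type replicate 2 or without either mutant replicate. The list just missed the threshold (adjusted p = 0.0506, and 0.88 with an estimated correlation, with alternatives from 7.0e-04 to 0.88). The rows opposite 4 further mitotic genes all fell: that of ncd, a spindle motor (CG7789), by 1.83 (SE 0.25), that of the kinase gene aurA (CG12213) by 1.26 (SE 0.20), that of Klp61F (galene) by 1.14 (SE 0.20) and that of Bub3 (ppk19) by 1.08 (SE 0.18). In that order, only 8.85, 5.87, 14.26 and 14.13% of the row's length overlapped the mitotic gene.

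Of the own rows of 11 meiotic genes, 3 fell (rec, whose opposite gene is alpha-Man-IIb, nod and mtrm) and 1 rose (nenya), with a median of −0.24 (list adjusted p = 0.352). Adjusted over the list alone the counts were the same, and with library totals alone 6 fell and 1 rose. The matrimony gene mtrm, with no opposite gene, had 12 and 27 counts in wild type and 8 and 2 in the mutant. Of 6 rows opposite a meiotic gene, 4 fell: that of sub, a meiotic spindle kinesin (Ir54a), by 2.02 (SE 0.19), that of nod (pkm) by 1.74 (SE 0.21), that of c(2)M, a synaptonemal complex protein (CG5861), by 1.26 (SE 0.26) and that of spn-B (NK7.1) by 0.65 (SE 0.19). In that order, 26.56, 6.76, 12.43 and 5.54% of the row's length overlapped the meiotic gene. Read from opposite rows, a choice made after the data were seen, the mitotic and meiotic lists both passed (adjusted p = 7.4e-04), but not with an estimated correlation (adjusted p = 0.348). The calls of nod and mtrm were lost without wild type replicate 2 or mutant replicate 2, and that of NK7.1 without either mutant replicate.

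Maternal and germline genes moved both ways. The row opposite nanos, CG11779 (3R, 19154405 to 19159878), went from 3775 ± 151 to 843 ± 19.6 CPM (log2 fold change −2.16, SE 0.13, adjusted p = 3.1e-07), whereas the own row of nanos rose by 0.63 (SE 0.18), a call lost without wild type replicate 2 or either mutant replicate. The posterior determinant osk rose on its own row by 1.06 (SE 0.34), a call lost without wild type replicate 1 or mutant replicate 1, and on the row opposite it, asRNA:CR44020, by 1.16 (SE 0.21). The row opposite exu (galla-1) fell by 0.96 (SE 0.15), and of 5 rows opposite a gene of oocyte polarity and maternal mRNAs 2 rose and 2 fell. Of 27 tested genes of oocyte polarity and maternal mRNAs, 4 rose and 4 fell, also when adjusted over the list alone. The list's median of 0.13 and camera's downward direction differed in sign (adjusted p = 0.911). With library totals alone 1 rose and 9 fell, and among the 15 rows without opposite-strand exons 3 fell and none rose. Of 16 germline stem cell and cyst genes, nanos alone passed the test and none did when adjusted over the list alone (list adjusted p = 0.866). Among 24 piRNA pathway genes, 5 fell and 1 rose, and 4 fell and none rose when adjusted over the list alone (median −0.28, list adjusted p = 0.223). Scaled by library totals alone, 12 fell and none rose, and among the 11 rows without opposite-strand exons edgeR called none. The piRNA genes that fell included mino (opposite gene NSD), by 1.48 (SE 0.15), and vret (opposite gene CG6985), by 0.82 (SE 0.20), a call lost without mutant replicate 1. The row opposite vret changed by −0.18 (SE 0.21) and was not called. Those opposite piwi and daed were not called either, and that opposite tapas (MED8) rose by 1.12 (SE 0.24).

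The DNA replication list had 1 row higher and 1 lower among 20, also when adjusted over the list alone (list adjusted p = 0.561), and 1 higher and 8 lower with library totals alone. E2f2 (opposite gene Mpp6) rose by 2.02 (SE 0.44) and Orc6 (opposite gene Sting) fell by 1.29 (SE 0.25). Of 8 rows opposite a gene of this list 2 fell and none rose, and 3 fell and 1 rose when adjusted over the list alone. Those opposite Orc1 (PIG-G) and Mcm7 (asRNA:CR45871), which act in replication licensing, fell by 1.60 (SE 0.19) and 1.05 (SE 0.13). The row of PIG-G overlapped Orc1 over 3.61% of its length, and asRNA:CR45871 overlapped Mcm7 over 89.22%. Among 19 insulin and TOR genes, Ilp6, an insulin-like peptide (X, 2331493 to 2334658, no opposite gene), had 4 and 11 counts in wild type and 63 and 43 in the mutant and rose 6.88-fold (SE 0.39 on the log2 scale). ImpL2, an insulin antagonist, rose by 1.66 (SE 0.48), Ilp8 (opposite gene CG7730) fell by 2.23 (SE 0.32) and chrb fell by 0.75 (SE 0.26). The call of ImpL2 was lost without wild type replicate 2 or either mutant replicate and that of chrb without any of the 4 libraries. Adjusted over the list alone, 2 rose and 1 fell (list adjusted p = 0.726), and with library totals alone 1 rose and 5 fell. The receptor gene InR was not called, with 15 and 22 counts in wild type and 18 and 15 in the mutant.

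In the cell death list, the caspase gene Dronc (3L, 9968479 to 9971002, no opposite gene) fell from 46.3 ± 15.5 to 10.7 ± 0.841 CPM (log2 fold change −2.09, SE 0.38). Among the 4 rows that rose (5 higher and 1 lower when adjusted over the list alone), Strica, Dark and Dcp-1 overlap Pngl, asRNA:CR44390 and pita on the other strand. The row opposite Dark, with 85.68% of its length overlapping Dark, was not called (log2 fold change 0.03, SE 0.15). Nor was that opposite Strica (0.33, SE 0.35), while those opposite lok (vls) and PolZ1 (Nop17l) fell. The call of Dark was lost without wild type replicate 2 or mutant replicate 1 and that of Dcp-1 without wild type replicate 1 or either mutant replicate, and the list of 11 was not called by camera (adjusted p = 0.682). Fry called it upward (adjusted p = 0.0418, with alternatives from 0.0418 to 0.88), though its median of 0.38 turned to −0.55 among the 4 rows without opposite-strand exons and to −0.07 with library totals alone, where 1 rose and 3 fell. Hsp68 (opposite gene CG6000) fell 11.4-fold and Hsp27 (opposite gene CR43483) fell by 1.40 (SE 0.21), while Hsp60A, with no opposite gene, rose by 1.74 (SE 0.33). Of 15 heat shock rows 4 rose and 3 fell, also when adjusted over the list alone (list adjusted p = 0.752), and 2 rose and 4 fell with library totals alone. Of 13 genes tied to ribosomal protein loss and the integrated stress response, 2 rose and 4 fell, also when adjusted over the list alone (list adjusted p = 0.404). They included Xbp1, which rose by 1.63 (SE 0.45), a call lost without wild type replicate 1 or mutant replicate 2, and GstD1, which fell by 1.21 (SE 0.28), a call lost without mutant replicate 2. Mitochondrial ribosomal proteins (6 higher, 7 lower of 39, list adjusted p = 0.682) and nuclear genes of oxidative phosphorylation (7 higher, 7 lower of 41, list adjusted p = 0.866) went both ways. Adjusted over the list alone, 6 rose and 8 fell among the former and 10 rose and 9 fell among the latter. With library totals alone the counts were 3 higher and 17 lower, and 3 higher and 15 lower, and the median of the latter turned from 0.11 to −0.33. Of 8 tested early follicle cell genes, br alone rose, by 1.86 (SE 0.35, opposite gene Mur2B), also when adjusted over the list alone (list adjusted p = 0.451), and the list of border cell genes, with 4 tested, was not called (adjusted p = 0.536).

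Markers of other tissues were mostly too low to test. Among 4 tested genes of the hemocyte list, the collagen IV genes Col4a1 and vkg rose 5.62-fold and 2.73-fold, also when adjusted over the list alone (list adjusted p = 0.223). Neither has an opposite gene, and which cells their transcripts came from was not tested. Of 6 muscle genes Prm fell by 1.59 (SE 0.43), a call lost without wild type replicate 1 or mutant replicate 2 (list adjusted p = 0.866, with the same count when adjusted over the list alone). Of 3 immune genes PGRP-SD, which overlaps CG7492, fell by 1.48 (SE 0.25), also when adjusted over the list alone, with a list median of 0.20 against a downward camera direction (list adjusted p = 0.631). Of the testis list 2 genes and of the oviduct list 1 gene could be tested, with medians of 0.24 and 0.13, and edgeR called none of them. No gene encoded by the mitochondrial genome was among the matched rows.

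**Figure D3:**
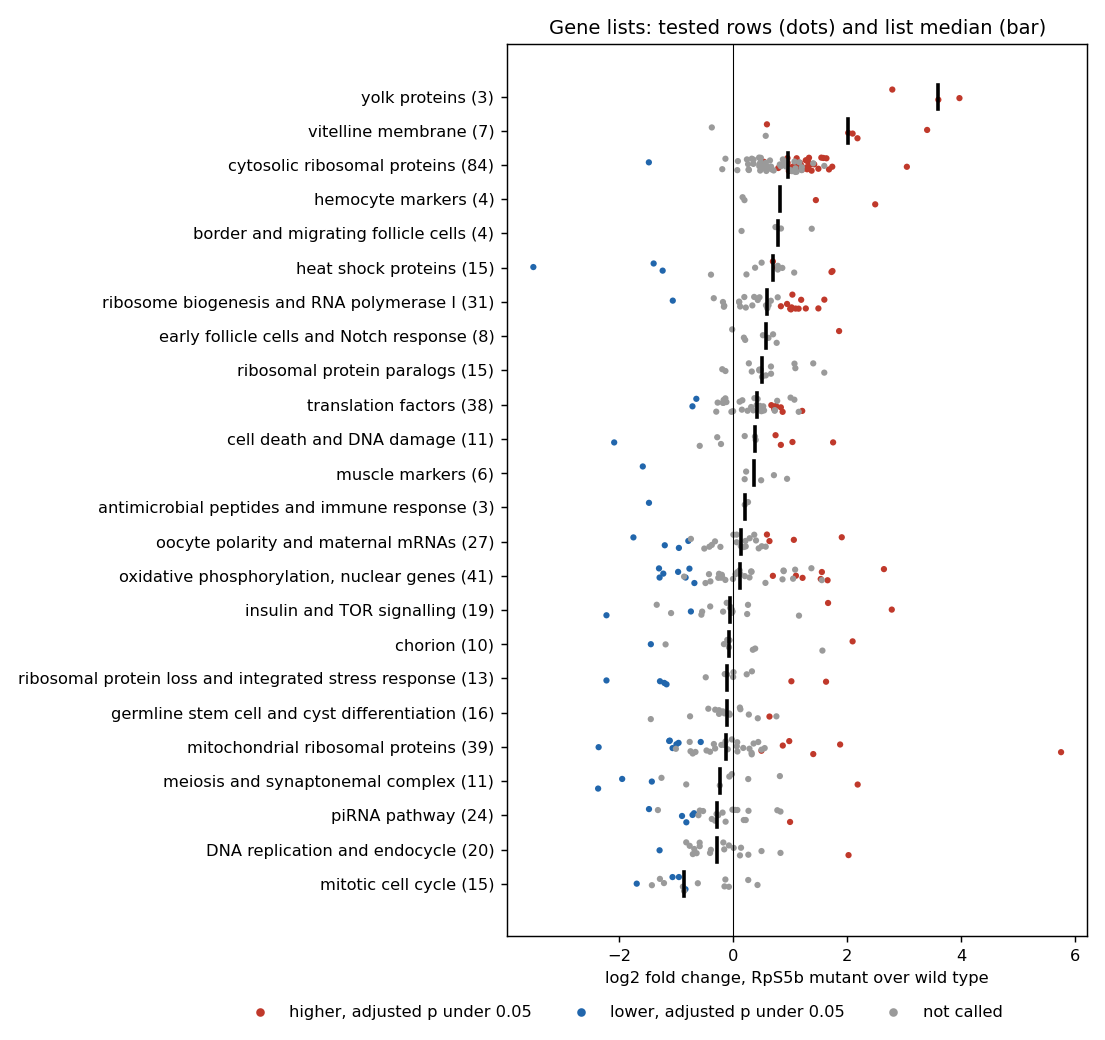
Each dot is a tested row and its log2 fold change (mutant over wild type), grouped by gene list with the number of tested rows in brackets, and black bars are list medians; red dots rose and blue dots fell. The medians run from −0.86 for mitotic genes to 3.60 for yolk proteins.

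The largest changes were in genes outside the lists. A difference in genetic background between the groups was not tested and cannot be told apart from the mutation in these rows. ChLD3 (2L, 16738850 to 16742610, opposite gene LSm7), a chitin deacetylase-like gene, had 1 and 0 counts in wild type and 1076 and 978 in the mutant, a scaled ratio of 2025 with a counting interval of 363 to 80017. The pigmentation gene yellow (y, X, 356509 to 361245, no opposite gene) had 5 and 3 counts against 727 and 479, a ratio of 149 (75.2 to 345). Reepl1 had 0 and 1 against 248 and 157, a ratio of 399 (71.3 to 15808), and the non-coding row lncRNA:CR40469 (X, 122493 to 122706) 16 and 47 against 4783 and 5912, neither with an opposite gene. Naxe (opposite gene CG2972), CG7213 and CG46303 (opposite gene Sec20) had no counts in wild type and were at least 27.6-fold, 19.4-fold and 18.7-fold higher in the mutant, against a floor of 3 counts over the group. CG1523 (opposite gene Prp39) had 0 and 1 against 122 and 75, and phr (opposite gene Prosalpha1) and CG18853 (opposite gene Prosalpha1R) had nearly equal counts in every library, so the increase is uncertain for either. In the other direction CG31955 (2L, 3712154 to 3713105, no opposite gene) had 125 and 166 counts in wild type and 0 and 1 in the mutant, a ratio of 295 (52.6 to 11699). Surf1 (opposite gene sgl), an assembly factor of cytochrome oxidase, was lower by a ratio of 69.8 (33.6 to 175), and CG5644 (opposite gene Srp68) had 227 and 319 counts against 8 and 5. The non-coding row lncRNA:CR34335 fell by 4.29 (SE 0.16). CG12519, CG14096 and CG18294 (the last opposite asRNA:CR46047) had the same 4 counts (96, 85, 2 and 3), so their decrease is uncertain for any of them. The transcription factor gene trem (opposite gene CG4854), CG17217 (opposite gene CG6583) and CG3857 (no opposite gene) completed the 10 largest decreases.

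The counts of changed rows depended on scaling. With library totals alone 394 rows rose and 1601 fell, the median of all rows shifting by −0.45 on the log2 scale, and with the header totals 617 rose and 923 fell (shift −0.15). Fitted among themselves, the 2272 rows without opposite-strand exons gave 182 higher and 167 lower, and 329 of these 349 were called in the same direction in the fit of all rows.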

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

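The fit of rows without opposite-strand exons, the header totals and the reading from opposite rows were chosen only after the data were seen, and the other alternatives before. The RpS5b level stayed lower in the mutant and past the test in every alternative that gave an adjusted p, with log2 fold changes of −4.37 to −3.33 (DESeq2 gave no adjusted p for it). Of 1833 alternative values of the 128 named genes other than RpS5b, 1608 stayed on the same side of the threshold, 211 lost the call, 14 gained it and 0 changed direction. Against 1460 genes changed in RpS5b mutant ovaries (801 higher, 659 lower), a required change of more than 1 on the log2 scale left 248 (163 and 85), which its construction explains. Sums over all rows of a gene gave 914 (508 and 406), DESeq2 755 (340 and 415), and the smaller set of rows without opposite-strand exons 349 (182 and 167). Library totals alone gave 394 higher and 1601 lower. Leaving out 1 library, so that a lone sample is assumed to vary like the other group, gave 922 to 1333 changed rows and 378 to 652 lower ones. The replicate block gave 1104 higher and 948 lower, and 67 higher cytosolic ribosomal proteins. Deviations of same-numbered libraries correlated at 0.243 over 5031 rows, but with 2 pairs and no source for a pairing in the labels the libraries share only a number. Of the gene lists, 3 were called by camera, 5 with no low-count filter, 3 to 6 when 1 library was left out, and 0 with an estimated correlation, which was also 0 for opposite rows and for rows without opposite-strand exons. Fry called 1, the cell death list, upward. Apart from the required minimum change, the cause was not tested. DESeq2 was not run for the gene list tests. Of 17533 genes 5031 had enough counts on their row to be tested, which limits all of these results.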

Other observations

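Of the tests below, the correlation across pairs, the even background test and the matched lists were chosen before their results were seen, and the others after. The genes of this paragraph were also picked after their values were seen, so they say nothing about a gene group. The laminin gene LanB1 rose by 2.37 (SE 0.41) and the perlecan gene trol by 1.84 (SE 0.33), and dpy, which encodes a large apical matrix protein, rose by 2.62 (SE 0.38). None of these has an opposite gene. TFAM, a factor of mitochondrial DNA, rose by 2.35 (SE 0.31), Pepck1 had 0 and 2 counts in wild type and 50 and 62 in the mutant, a ratio of 55.2 (counting interval 14.9 to 462), and Gadd45 had 0 and 2 against 52 and 33, a ratio of 41.9 (11.2 to 352). Among maternal genes without an opposite gene, me31B fell by 0.79 (SE 0.19), a call lost without mutant replicate 1, and Tl fell by 1.75 (SE 0.45), a call lost without wild type replicate 2. Near RpS5b, 27 of 102 rows within 1 Mb were called, or 26.5% against 29.1% elsewhere (Fisher's exact test, two-sided p = 0.659).

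Most counts lay on rows with an exon of another gene on the opposite strand. Even background, such as genomic DNA, was argued against by ribosomal protein rows without opposite exons holding 1222.4 times the median counts per kb of testis rows. Antisense RNAs from these loci stay open: the median ratio of 50.26 in counts per nucleotide between non-coding rows and the own rows of the coding genes (73 pairs) restates the pattern. Reads counted in the orientation opposite to their transcript are a candidate explanation, as the changes of both rows correlated across 31 pairs (r = 0.637), but r was 0.344 without the 2 farthest pairs, so the support is partial, and antisense RNAs that change with their mRNA would give such a correlation too. Own rows of 92 cytosolic ribosomal protein genes held only 0.026 to 0.051% of a library's header total. Such small shares go with reads counted in the opposite orientation. So does the 2.17 to 2.75% of header totals held by gene rows of any kind, but other causes of a low share were not tested. Strand thus stays open, and with it which gene of each overlapping pair a value belongs to. How much of a gene's mRNA its own row counts stays open too.

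All 3 yolk protein rows and 5 of 7 tested vitelline membrane rows were higher in the mutant. The calls of both lists were lost with an estimated correlation and with fry. Whether choriogenic chambers were kept in the mutant samples stays open. The chorion rows did not rise like the vitelline membrane rows. Their median was −0.072 (SD 1.079), below the bound of 2 by more than its SD. That bound followed the vitelline membrane median, and the wording was narrowed to the last stages, both after these values were seen. Counts were also low on chorion rows such as Cp15 (20 and 16 in wild type, 9 and 7 in the mutant). For the yolk rows, fat body tissue in the mutant samples cannot be told apart from a change in the ovary: 2 of 18 fat body rows passed the low-count filter (median 0.608). With no filter 13 had a median of 0.17 (adjusted p = 0.771) and with summed rows 5 had 0.75 (adjusted p = 0.531), below the yolk median of 3.60, but most of these lie near the floor. Fat body does not use vitelline membrane genes, so their list median of 2.017 (SD 1.286) argues against fat body as the source of that part. That reading was chosen after the values were seen, and counts were few for Vm26Aa and Vm34Ca. A larger share of earlier, yolk-forming chambers in the mutant samples, whether from dissection or from the mutation, was not tested and stays open.

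Of 84 tested cytosolic ribosomal protein rows, 37 were higher in the mutant and 1 was lower. The list's call was lost with an estimated correlation and with fry. Row length or abundance was argued against by matched random lists, of which 0.0% of 10000 reached the observed median of 0.895 (highest 0.279). Scaling overlapped and free rows together was argued against by the median of 0.895 when free rows were scaled among themselves. Variation of the whole list between libraries cannot be told apart from the mutation: the gap between groups was 1.27 times the larger gap between replicates (0.891 against 0.657 and 0.703). That test replaced an earlier one, of wild type replicate 1 alone, after its value (a median of 0.668 without that library) had been seen. A different mix of egg chamber stages in the mutant samples was not tested for these rows and stays open.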
